A study of Saccharomyces cerevisiae with 23 samples.

How the data were processed

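PAR-CLIP, a method that crosslinks RNA to a protein through the photoreactive base 4-thiouracil and reads the crosslinks as T-to-C changes, was done on 23 yeast proteins that each carried a TAP tag, with 1 library per protein. Per the labels, cells grew at 30 °C in minimal medium with 10 mg/l uracil, 2% glucose and 100 µM 4-thiouracil, received another 900 µM for 4 h, and were irradiated with 12 J/cm2 at 365 nm. The strain label was BY4741 for 22 libraries and RS453 for that of Tho2. The submitters' processing notes name Bowtie 0.12.7 and the sacCer3 build.

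Each deposited file lists sites for 1 library, with chromosome, position and strand. The authors give each site a p-value, which was under 0.005 in every file, and an occupancy, which is a ratio whose definition the labels do not state. The deposited occupancy was not scaled to the library: at 107234 sites listed in at least 8 libraries, 99.9% had values in whole-number ratios to each other within a relative tolerance of 2e-05. The files give no read counts, so the sequencing depth is unknown, no interval that needs it is given, and the number of sites stands in for it. Libraries held between 25493 sites (Snp1) and 801430 sites (Mud2). Whether positions count from 0 or 1 is not stated, so distances may be off by 1 nt.

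Sites were assigned to 6430 nuclear genes whose strand follows from the systematic name. The annotation holds gene spans from start to stop codon and no introns, and no genome sequence was used here. Genes with introns were therefore approximated by the 166 protein-coding spans of up to 4000 nt whose length is not a multiple of 3. This leaves out genes whose intron length is itself a multiple of 3, such as RPL18B, RPL26A, GLC7 and PHO85, so these count among the other genes. A site's weight was its occupancy. The intron-gene share was the percent of sense occupancy in coding spans that lay in intron genes. The 3' end share was the percent of the occupancy from 100 nt before the start codon to 250 nt after the stop codon that lay after the stop codon, in 3712 genes of at least 800 nt whose length is a multiple of 3 and whose span holds no other gene on the same strand. The 5' end share was the part up to base 150 of the same span. The U1 snRNA share was the percent of all occupancy, compared as log2 after adding 0.001. Far over near occupancy was log2 of bases 251 to 600 over bases 1 to 150 of intron genes, less the same value in genes of at least 800 nt whose length is a multiple of 3. The strongest site was the site of highest occupancy in each intron gene with at least 5 sites, and its distance from the start codon was summarised by the median; this measure was added after the data were examined. The intron-gene share and far over near occupancy took the place of the planned share in introns and of the planned windows once the annotation was found to hold no introns.

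Proteins were grouped by textbook function, not by the labels. The splicing class held 7 proteins, of which 4 belong to the U1 snRNP (Luc7, Mud1, Nam8, Snp1) and 3 act at the branch point side (Msl5, Mud2, Ist3). The 3' processing class held 4 (Cft2, Mpe1, Yth1, Rna15), the export and TREX class 9 (Hpr1, Tho2, Sub2, Yra1, Mex67, Gbp2, Hrb1, Npl3, Nab2), poly(A) or U-rich binding 2 (Pab1, Pub1) and cap binding 1 (Cbc2). Spreads are therefore between different proteins of a class and not between replicates. Batch codes in the file names put every export and TREX library in batches without a splicing or 3' processing library, so these differences cannot be told apart from batch. Splicing and 3' processing libraries share 2 batches.

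Class means were compared by two-sided exact permutation tests, and the similarity of libraries (Spearman correlation across genes) and the own-transcript comparison by permutation tests with 100000 resamples. The planned fit for counts needs read counts, so genes were compared with limma 3.58.1 (R 4.3.3) on log2 of each gene's share of the coding occupancy in parts per 1e6 (ppm) plus 10, for genes with a mean of at least 20 ppm, with all 23 libraries in 5 classes, a trended prior and Benjamini-Hochberg adjustment at 0.05. The comparison of splicing with 3' processing was added after the data were examined. The comparison of 3' processing with export used spans extended by 250 nt after the stop codon. For 13 gene lists, the share of occupancy was compared in 26 exact tests adjusted together; the lists were glycolysis, histones, chaperones, translation factors, respiratory chain and ATP synthase, ergosterol synthesis, cell wall and plasma membrane, amino acid synthesis, ribosome biogenesis, ribosomal proteins, mitochondrial ribosomal proteins, intron-containing ribosomal protein genes and other intron-containing genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest, and matplotlib 3.10.9 drew the plots. In a test on simulated data, limma recovered 83.3% of genes given a log2 change of 3.00 and 52.2% of those given 2.00 for splicing against export, with 1 false call, and 77.3% and 25.4% for 3' processing against export, also with 1 false call. Of genes given a log2 change of 1.00 it recovered 1.49% in both. The simulated noise was independent between genes and libraries, without batches, and changed genes were drawn from those above the median level. These rates therefore do not cover weakly listed genes, and the false calls do not cover batch or other structure of the real libraries.

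Named genes follow a rule fixed before the data were examined, apart from the replacements given below. It takes the 12 genes of smallest p in each direction of both planned gene comparisons, the 4 members of highest mean of each list, the 10 intron genes of highest mean share in the splicing libraries, the genes of the 23 tagged proteins, the spliceosomal snRNAs, and for each library the 3 genes with the highest ratio to the median of the other libraries. The last part asked for a minimum of T-to-C reads, which the files do not give, and was replaced by a minimum of 20 sites after the data were examined. The rule also named 10 introns, for which intron genes stand here, and p-values of the planned fit for counts, for which those of limma stand. Members of lists that are named because they passed, and export factor genes singled out by their change, were chosen after their values were seen. Alternatives changed the weight of a site, the threshold on p, windows and gene sets, the pseudocount, the scaling, the number of sites as a covariate, the batch and the libraries included. Left out for lack of counts, introns or sequence were the share in introns proper, windows at splice sites and branch points, 3 motif searches, fits for counts with other normalizations, the minimum of T-to-C reads, and coverage per site.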

Results

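The data are maps of crosslink sites for 23 proteins that bind yeast messenger RNA between transcription and export, each in 1 library, so no value below has replicates of the same protein. The 23 files listed 6454521 sites at 2419404 distinct positions, of which 971520 were listed in 1 library. The median library held 233513 sites, the smallest 25493 (Snp1) and the largest 801430 (Mud2). Protein-coding spans took between 10.4% of the occupancy (Yth1) and 82.8% (Yra1). The 250 nt after the stop codon took 62.8% in Yth1 and 2.56% in Yra1. Antisense sites took 27.0% in Rna15 and 2.39% in Ist3.

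A first question, given the title of the series, is which proteins meet unspliced RNA. Without annotated introns it could not be answered, since whole spans of intron genes, exons included, do not tell unspliced from spliced RNA. The values below answer the narrower question of which proteins have more occupancy in intron genes. Genes with introns took 14.95% ± 5.24 (SD, n = 7) of the coding occupancy in libraries of splicing factors and 2.28% ± 0.811 (SD, n = 16) in the other libraries. All 7 splicing libraries lay above the 16 others. The lowest splicing value was 6.00% for Msl5, the branch point binding protein, and the highest was 22.4% for Ist3, a subunit of the U2-associated RES complex. Among the other proteins Nab2, a poly(A) binding export factor, was highest with 3.66%, and Mex67, the main export receptor, lowest with 1.11%. The 4 U1 snRNP proteins reached 16.1% ± 2.26 (SD, n = 4). The difference of 12.7 percentage points gave an exact permutation p of 8.16e-06, the smallest that the 245157 splits allow.

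Within batches the difference was 10.4 percentage points between Mud2 and Yth1, and 7.78 between Luc7 and Msl5 on one side and Cft2 and Rna15 on the other. On batch-centred values it was 8.66 with an exact p of 0.167, the smallest this smaller design allows. Counting each site once gave 6.11 and leaving out ribosomal protein genes gave 8.31, both in the same direction.

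**Figure D1:**
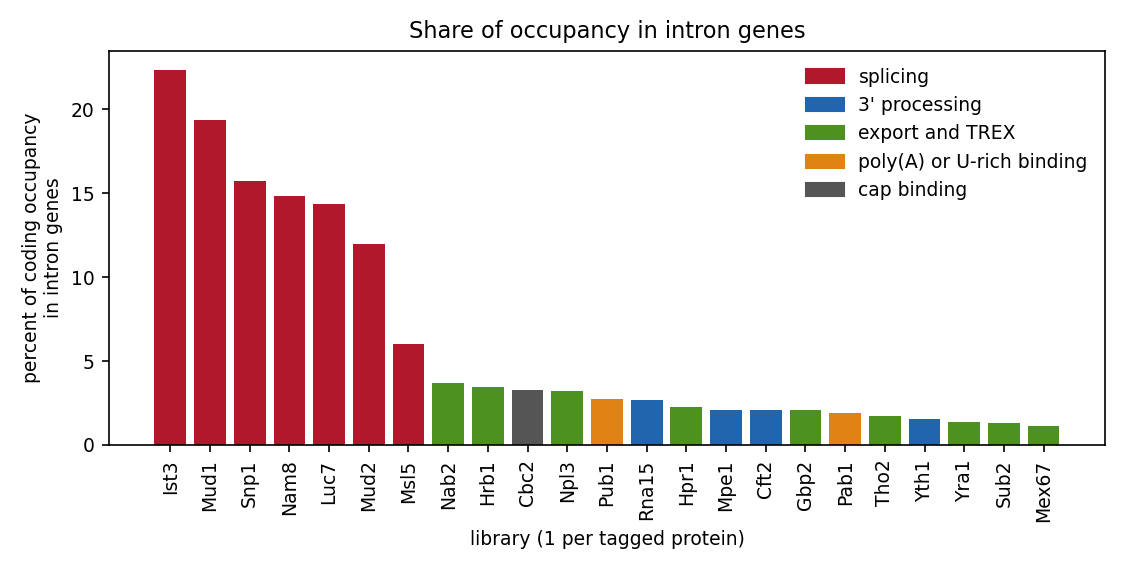
Bars give the percent of coding occupancy in intron genes for each of the 23 libraries, coloured by class of protein. The 7 splicing libraries run from 22.4% (Ist3) to 6.00% (Msl5) and all lie above Nab2 at 3.66%.

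The intron genes of highest mean share in the splicing libraries were led by MPT5, which encodes an RNA-binding repressor of the PUF family (chromosome VII, 167352 to 170571), with 4922 ± 3455 ppm (SD, n = 7) against 1495 ± 843 (SD, n = 16) in the other libraries. PFY1, the gene of the actin-binding protein profilin (chromosome XV, 552298 to 552887), had 3256 ± 2188 against 139 ± 89.7 ppm, a ratio of 23.5. UBC4, which encodes a ubiquitin-conjugating enzyme (chromosome II, 406628 to 407169), had 2356 ± 1628 against 122 ± 94.1. RPL36B, RPL37B, RPS19B and RPL33B, all genes of ribosomal proteins, had ratios of 20.6, 13.7, 12.8 and 10.7. RCF3, PAL2 and YOP1 completed the 10 with ratios of 7.59, 3.74 and 13.9. MPT5 did not pass the gene comparison of splicing with export libraries, with a log2 change of 1.74 (adjusted p 0.0858, limma).

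A second question is whether U1 snRNP proteins, which bind the 5' splice site, and proteins of the branch point side sit at different places of these genes. Among splicing libraries the strongest site in intron genes lay nearest the start codon for U1 snRNP proteins, with medians of 55.0 nt (Luc7), 65.0 nt (Nam8), 70.0 nt (Mud1) and 73.0 nt (Snp1). For the branch point side the medians were 124 nt (Msl5), 152 nt (Mud2) and 161 nt (Ist3). Cbc2, outside the class, had a median of 68.5 nt. In RPL36B the strongest site lay 41 nt from the start codon in Luc7 and Nam8 and 43 nt in Snp1, but 234 nt in Mud2 and 244 nt in Ist3; in Mud1 it lay at 212 nt and in Msl5 at 59 nt. In RPS19B it lay at 41 nt in Luc7 and Nam8, at 65 nt in Mud1 and at 71 nt in Snp1, against 431 nt in Mud2 and 234 nt in Ist3, but Msl5 had the 71 nt of Snp1, so neither gene parts the classes fully. Other genes parted less: in RPL37B the site lay at 207 nt in Luc7, Mud1, Nam8 and Mud2, and in RPL33B at 39 nt in Mud1, Nam8 and Snp1 and at 41 nt in Mud2. These examples were chosen after their values were seen. The class means were 145 ± 19.5 nt (SD, n = 3) and 65.8 ± 7.89 nt (SD, n = 4), and the difference of 79.6 nt had an exact permutation p of 0.0571, the smallest that 35 splits allow. With ribosomal protein genes left out the difference was 45.8 nt, and with these alone 229 nt. Less the median in genes of up to 1500 nt whose length is a multiple of 3, the difference was 35.2 nt with an exact permutation p of 0.514. Intron genes whose span is a multiple of 3 were not removed from that set.

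Far over near occupancy, which took the place of the planned windows at splice sites and branch points, did not separate the classes. Its log2 mean was -1.19 ± 0.49 (SD, n = 3) on the branch point side and -1.44 ± 0.20 (SD, n = 4) for U1 snRNP proteins. The difference of 0.25 had an exact permutation p of 0.457. Within the batch of Luc7 and Msl5 it was 0.43, and without Mud2 it was -0.0024. Before subtraction, the log2 mean in intron genes was -0.296 ± 0.447 (SD, n = 3) on the branch point side. For U1 snRNP proteins it was -1.30 ± 0.462 (SD, n = 4), and the ranges did not overlap. The genes of at least 800 nt used for subtraction parted the same way, with 0.891 ± 0.0714 (SD, n = 3) and 0.142 ± 0.288 (SD, n = 4). Neither difference was tested.

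U1 snRNA was listed far more in the libraries of its own proteins. It took 1.06% of the occupancy in Snp1, the yeast U1-70K protein, 0.493% in Mud1, the yeast homologue of the human U1 A protein, 0.143% in Nam8 and 0.108% in Luc7. The 19 other libraries had a mean of 0.00308% ± 0.00424 (SD, n = 19), against 0.451% ± 0.442 (SD, n = 4). The log2 difference of 6.57 had an exact permutation p of 2.26e-04, the smallest that 8855 splits allow. Counting each site once gave 2.53 with an exact p of 0.0337; with sites of p under 0.0005 alone the difference was 2.51 with an exact p of 0.0775, and within the batch of Luc7 it was 4.80. In the 4 U1 snRNP libraries the other spliceosomal RNAs were lower than U1 snRNA. In Ist3, where U1 snRNA took 0.0195%, U2 and U6 snRNA were higher, and over the 19 libraries outside the U1 snRNP the mean of U2 snRNA was 0.00707%. U2 snRNA reached 0.101% in Snp1 and 0.0551% in Ist3, U6 snRNA 0.0367% in Ist3, U4 snRNA 0.0154% in Snp1 and U5 snRNA 0.00653% in Snp1.

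The next question is which proteins meet the 3' end. The 4 proteins of 3' processing had 47.5% ± 25.9 (SD, n = 4) of their occupancy after the stop codon, against 10.4% ± 11.2 (SD, n = 19) in the other libraries. Yth1, the zinc finger subunit of the cleavage and polyadenylation factor, had 83.1%, and Rna15, the RNA-binding subunit of cleavage factor IA, 50.4%. Mpe1 had 29.1% and Cft2 27.5%, both subunits of the cleavage and polyadenylation factor. Outside the class, Pub1, which binds U-rich RNA, had 49.5%, and Pab1, the poly(A) binding protein, 28.2%. The highest 10 nt bin began 110 nt after the stop codon in Yth1 and Mpe1, at 120 nt in Cft2, at 150 nt in Rna15, at 80 nt in Pub1 and at 60 nt in Pab1.

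The difference of 37.1 percentage points had an exact permutation p of 0.00271. Within batches it was 73.5 between Yth1 and Mud2, and 32.6 between Cft2 and Rna15 on one side and Luc7 and Msl5 on the other; on batch-centred values it was 46.3 with an exact p of 0.167, the smallest that design allows. Counting each site once gave 16.9 with an exact p of 0.00678.

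**Figure D2:**
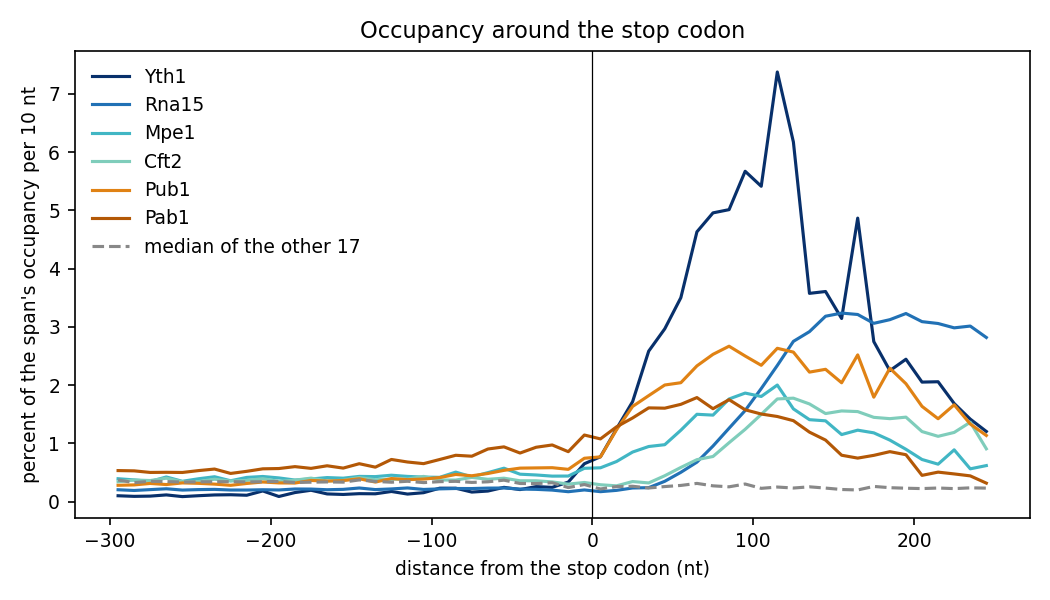
Lines give the percent of each library's occupancy in the analysed span per 10 nt, by distance from the stop codon in nt, for the 4 proteins of 3' processing, for Pub1 and Pab1, and as the median of the other 17 libraries. Yth1 peaks at 7.37% in the bin that begins 110 nt after the stop codon, and Rna15 at 3.24% at 150 nt.

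At the 5' end, Cbc2, the small subunit of the cap binding complex, had 36.3% of its occupancy up to base 150, with no test possible for 1 library. Luc7 was the single library above it, with 39.0%, and the median of the other libraries was 13.4%. The share of Cbc2 was 22.6% when each site counted once. Its order against Luc7 turned with equal numbers of sites, 44.0% against 43.5%, and with sites of p under 0.0005, 57.2% against 39.3%.

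Splicing and export libraries were compared gene by gene. In limma, 632 of 5358 genes differed, 260 higher and 372 lower in the splicing libraries. Of the 161 intron genes tested, 128 rose (79.5%, against 2.54% of the other genes, Fisher's exact p 7.54e-151) and 0 fell. Fisher's test takes genes as independent, although all calls come from the same libraries, so its p does not measure the spread between libraries. The median log2 change of all genes was -0.52, and with median-centred libraries 358 genes were higher and 219 lower and the median change was -0.12.

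The 12 genes of smallest p that rose held 8 intron genes by span. YOP1, which encodes an ER membrane-shaping protein, rose by 4.19 ± 0.46 (log2, SE; adjusted p 3.35e-06, limma), from 117 ± 82.0 (SD, n = 9) to 2240 ± 1058 ppm (SD, n = 7). UBC4 rose by 4.56 ± 0.50 and PFY1 by 4.57 ± 0.52. The ribosomal protein genes RPL42A, RPL26A, RPS23A, RPL36B and RPL18B rose by 4.03, 4.31, 4.45, 4.78 and 4.93. VMA9, which encodes a small subunit of the vacuolar proton pump, rose by 4.30, and YPR063C by 4.08. GLC7, the gene of the type 1 protein phosphatase, rose by 4.06, and PHO85, the gene of a cyclin-dependent kinase of phosphate signalling, by 3.35. RPL26A, RPL18B, GLC7 and PHO85 are known to carry introns although their spans are multiples of 3. YOP1 turned to -0.95 with sites of p under 0.0005.

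Among genes that fell, AGP1, which encodes a broad amino acid permease, had a log2 change of -3.84 ± 0.68 (SE; adjusted p 3.44e-04, limma), from 1313 ± 1064 (SD, n = 9) to 80.0 ± 70.2 ppm (SD, n = 7). PDC5, a minor pyruvate decarboxylase, had -2.39, and GSC2, a glucan synthase of the cell wall, -2.78. MCM2, a subunit of the replicative helicase, had -3.29, TFC6, a subunit of transcription factor TFIIIC, -2.78, and APL3, an adaptor of clathrin coats, -3.14. INO1, the inositol synthase gene, had -3.16, and PMA2, a proton pump gene, -2.72. MHO1, YHR033W, STR2 and NIT1 had -3.25, -2.84, -2.79 and -2.37.

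By list, all 57 intron-containing ribosomal protein genes rose, with a median of 3.26, as did 71 of 104 other intron-containing genes (85 adjusted over the list alone, where 1 fell) and 88 of 106 ribosomal protein genes (89 adjusted over the list alone, where 1 fell). RPL33B, RPL37B and RPS19B rose by 3.44, 3.92 and 3.94, and RCF3 and PAL2 by 3.37 and 2.23. In the respiratory chain list 5 of 22 fell (5 adjusted over the list alone), among them SDH1, a subunit of succinate dehydrogenase, at -2.73 and NDI1, an internal NADH dehydrogenase, at -1.93. In ergosterol synthesis 3 of 20 fell (4 adjusted over the list alone), including HMG1 and HMG2, the HMG-CoA reductases, at -2.66 and -1.83. In amino acid synthesis 3 of 43 fell (2 adjusted over the list alone), near the 7.16% of all tested genes outside the intron genes that fell. The median log2 changes of the respiratory chain, ergosterol and amino acid lists were -0.95, -0.47 and -0.69, against -0.52 over all genes. EFB1 and TEF4, which encode translation elongation factors and are known to carry introns, rose by 3.62 and 1.79, 2 of 12 translation factors with either adjustment. Of 15 chaperones 1 rose with either adjustment, SIS1 by 2.77, and of 27 ribosome biogenesis genes 1 rose, DBP2, another known intron gene, by 2.70, while 2 fell, unchanged when adjusted over the list alone. Of 67 mitochondrial ribosomal protein genes 2 rose, among them MRPL44 by 4.18, and 2 fell (1 and 1 adjusted over the list alone). No gene of glycolysis (18), histones (7) or cell wall and plasma membrane (22) passed with limma, over all genes or adjusted over the list alone.

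As shares of the coding occupancy, ribosomal protein genes took 10.7% ± 4.47 in splicing libraries (SD, n = 7) and 1.12% ± 0.950 in export libraries (SD, n = 9), with an exact permutation p of 1.75e-04 that became 0.00152 over 26 tests. Intron-containing ribosomal protein genes (6.06% against 0.648%) and other intron-containing genes (8.89% against 1.59%) had the same adjusted value. The respiratory chain list took 0.134% against 0.292% with an adjusted exact permutation p of 0.0182, which became 0.162 when each site counted once and 0.156 with equal numbers of sites. The other 22 tests did not pass, with translation factors closest at an adjusted p of 0.0536 (0.288% against 0.147%).

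The gene counts depended on the libraries included. Without Snp1 the count was 391. Without Mex67, Sub2 and Tho2, whose libraries list sites in genes deleted in BY4741, it was 237 (168 higher, 69 lower), and without Yth1 and Gbp2 it was 1220 (311 higher, 909 lower). With the number of sites as a covariate it was 342 (243 higher, 99 lower), with a pseudocount of 1 it was 412, with the 2 classes alone 952, with equal numbers of sites 92 (75 higher, 17 lower), and with sites of p under 0.0005 it was 9. All export libraries lie in batches without a splicing library, so class and batch cannot be told apart here.

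**Figure D3:**
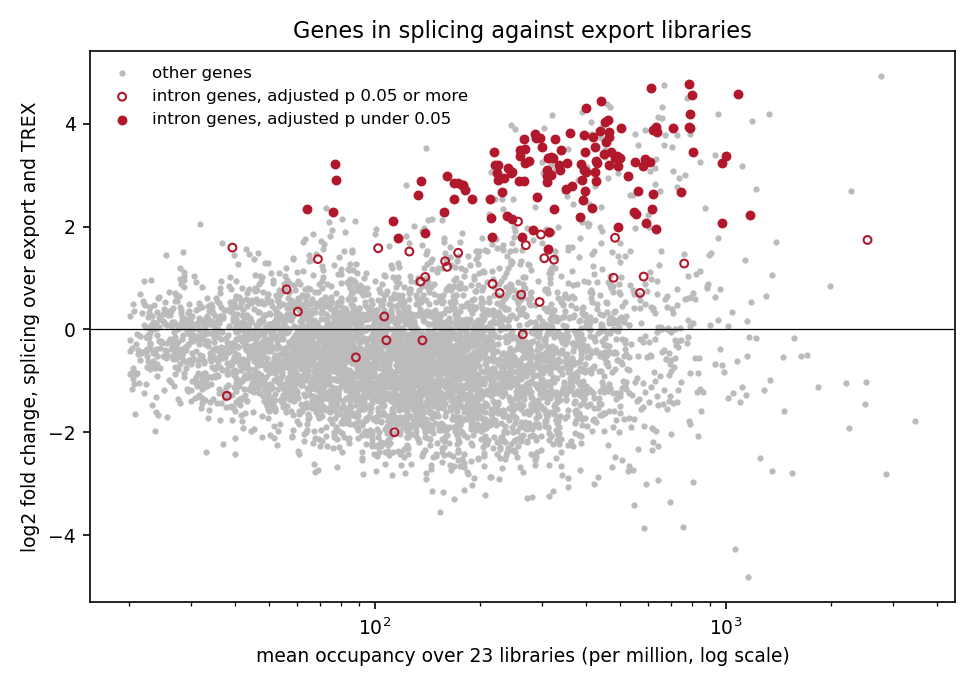
Each point is 1 gene, placed by its mean occupancy in ppm over the 23 libraries (log scale) and its log2 fold change in splicing over export and TREX libraries, with intron genes in red. Of the 161 intron genes 128 are filled, having passed the adjusted threshold, and all of these lie above 0.

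Splicing libraries were also compared with those of 3' processing, a comparison added because both classes share batches. In limma 413 genes differed, 221 higher and 192 lower in splicing libraries, and 116 of 161 intron genes rose, with 57 of 57 intron-containing ribosomal protein genes among them, and 1 intron gene fell. With the batch code as a covariate 92 genes differed (73 higher, 19 lower), 65 of them among the 413 and all 65 in the same direction. Counting each site once gave 75 genes, the 2 classes alone 201, a pseudocount of 1 gave 229, equal numbers of sites 22 and sites of p under 0.0005 gave 10. Of 106 ribosomal protein genes 87 rose and 1 fell (90 and 1 adjusted over the list alone), 4 of 22 respiratory chain genes fell (11 adjusted over the list alone, where 1 rose), and of 67 mitochondrial ribosomal protein genes 7 fell and 1 rose (12 and 1 adjusted over the list alone). The respiratory chain list took 0.983% of the coding occupancy in Yth1 and 0.170% to 0.248% in the other 3 libraries of 3' processing, and without Yth1 0 of its genes fell with either adjustment and 1 rose. Without Yth1, 5 mitochondrial ribosomal protein genes fell and 1 rose (11 and 1 adjusted over the list alone). The median log2 change of all genes was -0.25. YRA1 and HRB1, genes of export factors that are known to carry introns, rose by 2.29 and 2.29 (adjusted p 0.0188 and 0.0187, limma), while SNP1 fell, with a log2 change of -2.69 (adjusted p 0.0404). Against export libraries HRB1 rose by 1.48 (adjusted p 0.0481), and HPR1 and THO2, also genes of export factors, fell, with -3.03 and -1.42 (adjusted p 0.00954 and 0.0480). YRA1 did not pass there, with 1.28 (adjusted p 0.0857, limma). The export mean of THO2, 669 ± 496 ppm, includes 1738 ppm in the library of Tho2 itself.

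Between 3' processing and export libraries, measured with the 250 nt after the stop codon, 52 of 5460 genes differed in limma, 46 higher and 6 lower in 3' processing. The added 250 nt is the same for short and long genes. The mean 3' end share was 47.5% in 3' processing and 6.99% in export libraries. Gene length was not taken into account, and whether it sets these calls or the list counts below was not tested. UBI4, the stress-induced polyubiquitin gene, rose by 3.64 ± 0.62 (log2, SE; adjusted p 0.00741, limma), from 129 ± 91.9 (SD, n = 9) to 1606 ± 961 ppm (SD, n = 4). RPL9B, a ribosomal protein gene, rose by 3.48, PPH21, a catalytic subunit gene of protein phosphatase 2A, by 2.53, and IGO1, a regulator of that phosphatase, by 3.03. NHP6A, which encodes an HMG-box chromatin protein, rose by 3.99, and QCR7, a subunit of respiratory complex III, by 3.09. SNX3, a sorting nexin gene, rose by 2.92, BXI1 by 3.70, and THG1, the histidine tRNA guanylyltransferase gene, by 3.14. MRP49, a mitochondrial ribosomal protein gene, rose by 3.48, AIM46 by 2.62, and YNK1, a nucleoside diphosphate kinase gene, by 2.89. The 6 that fell were MSH3, a mismatch repair gene (-2.63), YOL075C (-2.56), BMT2 (-2.93), YCR101C (-2.42), DAL5, an allantoate permease gene (-2.72), and MRC1, a replication checkpoint gene (-2.47). Each of these 6 calls was lost in most of the 13 fits with 1 library left out: BMT2 and DAL5 in 12, MRC1 in 10, YCR101C and YOL075C in 9 and MSH3 in 8, so none of the falls is firm. Of the 12 genes that rose, YNK1 was lost in 2 of these fits and THG1 in 1. UBI4 and AIM46 turned to -1.74 and -0.96 with sites of p under 0.0005.

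By list, 2 of 10 histone genes rose (3 adjusted over the list alone), HTB1 by 2.72 and HHT1 by 2.59, and 2 of 16 chaperones (5 adjusted over the list alone), among them SSA1 by 3.18. Of 67 mitochondrial ribosomal protein genes 2 rose (14 adjusted over the list alone) and of 135 ribosomal protein genes 2 with either adjustment. The lists of the respiratory chain (22), amino acid synthesis (43), ribosome biogenesis (28) and other intron-containing genes (104) each had 1 gene that rose. Over the list alone these 4 gave 1, 2, 1 and 1 higher, with 1 lower in amino acid synthesis. No gene of glycolysis (18), translation factors (18), ergosterol synthesis (20), cell wall and plasma membrane (22) or intron-containing ribosomal proteins (57) passed over all genes in limma; adjusted over the list alone, 3, 4, 0, 1 and 0 were higher. Without Yth1, 3 glycolysis genes rose (13 adjusted over the list alone), 4 of 15 chaperones (9) and 1 of 67 mitochondrial ribosomal protein genes (5).

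The library of Yth1 held 22.1% of its coding occupancy in 10 glucose-repressed genes, against at most 0.0542% in the other 3 libraries of the class. Without Yth1 and Gbp2, 73 genes differed, 36 of them among the 52. The median log2 change of all genes was -0.17, and median-centred libraries gave 128 genes. The count of genes in limma was 0 when each site counted once (730 genes at an unadjusted p under 0.05) and 0 with sites of p under 0.0005 (725 genes), 3 with equal numbers of sites and 1 without Mex67, Sub2 and Tho2. Leaving out 1 library gave 14 (Cft2), 15 (Hpr1), 14 (Mex67), 22 (Rna15), 16 (Sub2), 16 (Tho2), 17 (Yra1) and 90 (Gbp2). Pseudocounts of 1 and 50 gave 4 and 194 genes, the number of sites as a covariate 109, and the 2 classes alone 103. All 9 export libraries lie in batches without a 3' processing library.

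Gene profiles were on average more alike within classes than between them. The mean Spearman correlation across 5358 genes, which are not independent replicates, was 0.576 over 64 pairs within classes and 0.436 over 189 pairs between them. The difference of 0.140 had a two-sided permutation p of 5.40e-04. Msl5 and Mud2, partners at the branch point, were closest at 0.900, followed by Sub2 and Tho2 at 0.870, by Hpr1 and Sub2 at 0.851 and by Hpr1 and Tho2 at 0.826, all members of TREX, and by Mex67 and its adaptor Yra1 at 0.823. The third protein of the branch point side, Ist3, had 0.386 with Msl5 and 0.387 with Mud2, below the mean between classes. Its closest library was Mud1, a U1 snRNP protein, at 0.673. Numbers of sites differ as well, with 476370 in Msl5 and 801430 in Mud2, but 66003 in Ist3 and 99384 in Mud1. Gbp2, with 65692 sites, had 0.102 with Ist3. Whether library size sets these correlations was not tested. Msl5 was also the closest library of Cbc2 (0.780) and Npl3 (0.767), which belong to other classes. Yth1 stood apart, its closest library being Cft2 at 0.230. The libraries of Cft2, Mpe1 and Rna15 were each closest to Hpr1, at 0.770, 0.673 and 0.764, and the mean within 3' processing was 0.408, below that between classes. Yth1 alone sets this, since the 3 pairs without it had a mean of 0.647, against 0.541 within splicing and 0.628 within export and TREX. The 1 pair of poly(A) or U-rich binding proteins lay at 0.413. Among pairs of different batches the means were 0.544 within classes (48 pairs) and 0.436 between (178 pairs); in pairs of the same batch they were 0.670 (16 pairs) and 0.439 (11 pairs).

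Whether proteins bind their own messenger was asked with the 23 tagged genes. The own library's share exceeded the median of the other libraries for 12 of 23, with a mean log2 ratio of -0.28 and a two-sided permutation p of 0.987. The mean rested on Snp1 and Yth1, whose genes were listed at 0 in their own libraries, so that the pseudocount sets their ratios: it was -0.0094 without Snp1, -0.056 without Yth1 and -0.087 with a pseudocount of 5. THO2 was the 1 gene ranked first in its own library, with 1738 ppm against a median of 347. Tho2 was also the single library with another strain label than the rest and with the tag named before the protein. Strain, tag and protein therefore cannot be told apart for this rank. YRA1 had 2016 against 486 and MUD1 781 against 273.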

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

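All tests of explanations below were chosen only after the results were seen, and no read counts are available to judge depth. Of 21 groups of libraries tested for a library far from its class, 4 had one, and chance gives about 1 in 20 groups. The flags of Yth1 and Gbp2 came from a list of glucose-repressed genes that was not among the planned measures, so that rate does not apply to them.

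The share of intron genes was higher in the 7 splicing libraries than in the 16 others. The tables argue against a few strong sites as the whole cause, since the difference was 6.11 with each site counted once. Each splicing library lay at least 4.30 percentage points above the other library nearest in number of sites. With all 7 above all 16 others no pairing could come out otherwise, so this is no test of depth. At nearly equal numbers of sites, Ist3 (66003) had 22.4% and Gbp2 (65692) 2.08%. Batch cannot be told apart from class for the export and TREX libraries, none of which shares a batch with a splicing library. Within the batches that hold both sides, the smaller difference was 7.78. These hold 3 splicing libraries and 3 of 3' processing, too few to decide, as the batch-centred exact permutation p of 0.167 was the smallest possible. The design's own difference, the function of the tagged proteins, may account for the higher share. It remains a hypothesis, as the pattern was found and tested on the same data with 1 library per protein.

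URA3, LEU2 and MET17 (MET15), 3 genes deleted in BY4741, were listed in the libraries of Mex67, Sub2 and Tho2 and in none of the 20 others, although Mex67 and Sub2 are labelled BY4741 as 22 libraries are. Reads from a wrongly assigned library of the batch would be likely to reach Hrb1, Nab2 and Pab1 too, which listed 0 sites in the 3 genes. A strain with another genotype than BY4741 stays open, since the 3 genes that raised the question cannot test it. Outside them, 1 of the 2 libraries, Mex67, departed from BY4741, an a strain, with 174 sites in alpha-cell genes and 4 in a-cell genes. Sub2 had 2 and 125, which does not speak against another a strain. Tho2, labelled RS453, had 3 and 148. The alpha-cell sites of Mex67 included 58 in MF(ALPHA)1 and 104 in STE3, against at most 9 on that list in any other library. A mixed culture with many a cells is argued against by 0 sites in MFA1 and MFA2 in Mex67, where the 8 libraries with at least as many coding sites listed 14 or more; the other a-cell genes, STE2 and BAR1, had 2 sites each there, so a small share of a cells stays open. No biological explanation beyond the strain was tested.

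In the library of Yth1, 10 genes that glucose represses took 22.1% of the coding occupancy, against 0.0371% to 0.0542% in the other 3 libraries of 3' processing; JEN1, ACS1 and ADH2 held most of it, and CAT8, with 1 site and 66.8 ppm, was lower than in Gbp2 (1684 ppm) and Tho2 (1363 ppm). Low depth is argued against by 877 sites in the 10 genes, more than the 378 of the highest other library. Small denominators of the occupancy are argued against by a share of coding sites, each counted once, that was 23.5 times that of the highest other library. Whether a culture low in glucose could account for it cannot be told: HXT1 and HXT3, transporters induced by glucose, had 49.4 ppm of the coding sites against 390.0 in the lowest other library, but this is 1 site, and the control genes LYS2, ADE2 and TRP1 were also lowest in Yth1 (148 ppm against 318 in the next library). The label gives 2% glucose, no biological explanation was tested, and a property of Yth1 itself stays open.

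The library of Gbp2 had 1.21% of its coding occupancy in the same 10 genes, against 0.0140% to 0.415% in the other 8 export and TREX libraries. Ist3 had 15.2% of its occupancy in tRNA genes, against 1.06% to 6.14% in the other splicing libraries. Hrb1 had a U1 snRNA share of 0.00499%, against 0.000297% to 0.00243% in the other export and TREX libraries. Sites on the mitochondrial chromosome, outside the measurements above, were listed for Mud2 (392) and Yth1 (429) and for no other library; 21S_RRNA held 137 and 140 of them, 15S_RRNA 65 and 102, and COX1 81 and 49.

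Splits of the same libraries into groups of the same sizes were drawn 100 times per gene comparison, the real one included. For splicing against export 1 of 100 called as many genes (632, highest other 44), and for 3' processing against export 1 of 100 (52, highest other 7), which excludes chance only for libraries that could be exchanged freely. These splits ignore batch, which cannot be told apart from class in both comparisons, and the 52 genes became 0 with each site counted once (730 at an unadjusted p under 0.05, limma) and 1 without Mex67, Sub2 and Tho2. For splicing against 3' processing 3 of 100 called as many (413), but splits that respect the batches number 12, too few for a share under 0.05, so chance is not excluded there. The highest other, 1102 genes, put Cft2, Luc7, Mpe1, Msl5, Mud2, Nam8 and Rna15 against Ist3, Mud1, Snp1 and Yth1, which points to a structure of the samples beyond their class. Number of sites moves with it, since the 4 libraries set apart have 25493 to 99384 sites and Luc7 alone among the 7 others has fewer than 99384, but whether it is the cause was not tested. With the batch code as a covariate the real split gave 92 genes.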

How the results depend on the processing

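Tests chosen only after the data were seen were those with equal numbers of sites, p under 0.0005, pseudocounts of 1 and 50, median-centring, the number of sites, doubted libraries and batch as a covariate, occupancy capped for genes, the strongest site, and splicing against 3' processing. Over 10 results, with the 2 left out whose tests cannot pass the threshold, 210 of 249 values under other settings kept their direction and side of the threshold, or a count within 1.5 times. Of 1122 values for 42 named genes 930 did so, 189 no longer passed and 3 reversed. Most values in both counts came from leaving out 1 library, and the own-transcript comparison, which never passed, is among those kept. With other changes, the intron-gene share and the 3' end share each held in 5 settings and not in 1. Gene counts stayed within 1.5 times in 5 settings for splicing against export (2 higher, 5 lower). They did so in 3 for 3' processing against export (4 higher, 5 lower) and in 7 for splicing against 3' processing (6 lower). With sites of p under 0.0005, YOP1 became -0.95, UBI4 -1.74 and AIM46 -0.96, and the cause was not tested. Batch-centring gave 8.66 for the intron-gene share and 46.3 for the 3' end share (exact p 0.167) and 4.80 for U1 snRNA (exact p 0.5), the smallest p that these fewer libraries allow. U1 snRNA gave 2.51 with p under 0.0005. The 5' end share of Cbc2 was 22.6 with each site counted once, 44.0 with equal numbers of sites, 57.2 with p under 0.0005 and 43.9 with windows 1.5 times as long. The cause was not tested for these or the counts below.

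Genes in splicing against export numbered 92 with equal numbers of sites, 9 with p under 0.0005, 952 with the 2 classes alone, 412 with a pseudocount of 1, 342 with the number of sites as a covariate, 237 without Mex67, Sub2 and Tho2, and 1220 without Yth1 and Gbp2. In 3' processing against export, limma gave 0 with each site once (730 at an unadjusted p under 0.05), 3 with equal numbers, 0 with p under 0.0005 (725 at an unadjusted p under 0.05), 103 with 2 classes, 4 and 194 with pseudocounts of 1 and 50, 128 median-centred, 109 with the number of sites, and 1 without Mex67, Sub2 and Tho2. Splicing against 3' processing gave 75 with each site once, 22 with equal numbers, 10 with p under 0.0005, 201 with 2 classes, 229 with a pseudocount of 1 and 92 with batch.

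Leaving out 1 library gave 11.4 to 14.2 for the intron-gene share, 25.3 to 43.8 for the 3' end share, 5.96 to 7.06 for U1 snRNA, and -0.0024 (Mud2) to 0.48 (Ist3) for far over near occupancy. The strongest site gave 71.8 to 90.5 nt, similarity 0.122 to 0.158, own transcripts -0.40 to -0.0094, and list shares 4 to 5. Gene counts ran from 391 (Snp1) to 925 (Msl5) for splicing against export and from 14 (Cft2) to 90 (Gbp2) for 3' processing against export, with Hpr1 15, Mex67 14, Rna15 22, Sub2 16, Tho2 16 and Yra1 17, and stayed within 1.5 times of 413 for splicing against 3' processing.

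Not run for lack of counts, introns or sequence were the share in introns, splice site windows, motif searches, count-based fits and normalizations, the minimum of T-to-C reads, reads in introns left out and an interval for Cbc2. Batch as a covariate could not be estimated against export, and the strongest site with p under 0.0005 gave no value. No paired analysis was possible because each protein has 1 library. Read depth is unknown.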

Other observations

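The genes that stood out in single libraries, by their share over the median of the other libraries, had no test, since each protein has 1 library. They were chosen by a minimum of 20 sites that was set only after the data were seen. In Hrb1 the cell wall mannoprotein genes TIR1 and TIR3 had 1362 and 1390 ppm, against medians of 19.2 and 53.7. In Pab1 the hypoxic genes ANB1 and AAC3 had 455 and 355 ppm and were listed at a median of 0 elsewhere. In Mud2, NDT80, the meiotic transcription factor gene, had 256 ppm, and in Msl5 AMA1, a meiotic activator of the anaphase-promoting complex whose gene carries an intron, had 212, both against a median of 0. HOP2, another meiotic intron gene, had 4489 ppm in Luc7 against a median of 4.76.

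In Ist3, COF1, the cofilin gene, had 7598 ppm against a median of 119, and DYN2, a dynein light chain gene, 3023 against 64.1; both carry introns. RPL18B had 25422 ppm in Snp1 and 6586 in Nam8 against a median of 199, and RPL35B had 5771 in Mud1 against 118. In Gbp2, OM45, a mitochondrial outer membrane protein gene, had 12532 ppm against 183. In Yra1, ADE17, a purine synthesis gene, had 1584 against 113. In Nab2, REX4 and EFG1, genes of ribosome maturation, had 246 and 229 against 7.05 and 10.2. In Yth1, RGI2, a respiratory growth gene, had 36754 ppm against a median of 0. Among the 10 glucose-repressed genes of that library, JEN1, a lactate permease gene, had 62317 ppm, ACS1, an acetyl-CoA synthetase gene, 53595, and ADH2, an alcohol dehydrogenase gene, 50219.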
